A study of Homo sapiens with 7 samples.

How the data were processed

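The data are 7 gene expression libraries of A549 cells sorted for β-galactosidase, 3 after doxorubicin (replicates 1 to 3) and 4 after cyclic stretch (replicates 4 to 7). Groups and replicate numbers come from the sample titles. The groups share no replicate number, so nothing pairs the samples and no block was fitted. Per the labels' protocols, RNA was isolated with Trizol and libraries were made with an Ion AmpliSeq kit for the human transcriptome, which amplifies a short stretch of each gene by PCR with gene-specific primers. Such reads carry no molecular identifiers, so counting precision is overstated where a transcript was amplified many times.

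The authors deposited a single table of whole numbers, read here as estimated counts per gene, not normalised between libraries. Per the submitters' processing notes, fastp 0.20.1 and Salmon 1.9 were used with the human build GRCh38. The notes give no role or order for these tools. Salmon gives fractional expected counts, so the whole numbers in the deposited table are taken to be rounded. The annotation release and the way transcripts were summed to genes are not given in the sources used here. The table has 14647 rows, and each row has at least 1 count in at least 3 of the 7 libraries. A total of 64 gene symbols stand in more than 1 row, many of them alternative haplotype copies of HLA genes, and their rows were summed. The row name Metazoa_SRP, a family name and no gene, was left out, and took at most 0.00861% of a library. This left 14535 genes. Coordinates (chromosome, start and end) and small nucleolar RNA hosts were taken from GENCODE release 29 on GRCh38. GC content came from the transcripts of that release, for 95.0% of the tested genes.

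Libraries were compared with R 4.3.3, edgeR 4.0.16 and limma 3.58.1. Genes were kept by edgeR's filterByExpr, scaled by TMM factors, and tested with the quasi-likelihood F-test (glmQLFit with robust estimation, then glmQLFTest), stretch minus doxorubicin, with Benjamini-Hochberg adjustment over 11230 genes and a threshold of 0.05. TMM factors ran from 0.443 in doxorubicin library 2 to 1.33 in stretch library 4. Standard errors are the absolute log2 fold change divided by the square root of F. CPM values use TMM-scaled library sizes, and log-CPM a prior count of 2. No 2 libraries agreed within sampling noise: the chi-square per degree of freedom over genes was at least 8.63 in all 21 pairs. No library was therefore a copy of another, and each was counted once. This check cannot tell whether libraries came from separate cultures or from the same RNA.

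Before the data were examined, 32 gene lists were fixed from textbook knowledge of A549 cells, senescence, stretch and doxorubicin. The 29 lists with at least 5 tested members were tested with limma's camera on log-CPM, with a preset correlation between genes of 0.01, again with an estimated correlation, and with fry. Camera compares a list with all other genes, and its p was adjusted over the 29 lists. Members were counted after adjustment over all genes and adjusted over the list alone. The genes to name were fixed by rule in the same way: the 10 largest differences in each direction among genes past the threshold with a mean of at least 10 CPM and groups that do not overlap, up to 4 members of each list with the lowest adjusted p, and 12 senescence and stretch genes whatever their values. Results of some genes, and of a list, are not reported here. A selection of 69 genes met by this rule was followed through every alternative, with 21 chosen after their values were seen, which are PDGFA, EIF4A2, TAF1D and genes named in the additional observations.

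The test was tried on counts simulated from the real genes' means, dispersions and library sizes, with seeded genes changed by known folds among 11135 tested. It recovered 4% of 2-fold, 65.3% of 4-fold, 93.9% of 8-fold and 96% of 16-fold changes between stretch and doxorubicin, and made 5 false calls among 133. In the simulation, genes varied independently and each gene had the same dispersion in both groups. The real doxorubicin libraries correlated less closely with each other (0.754 to 0.884) than the stretch libraries did (0.939 to 0.978). The recovery and false calls may therefore not carry over to the real data. Even in the simulation, most 2-fold differences were not detected.

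Alternatives planned before the data were examined were RLE and upper-quartile factors, library totals alone, no filter on low counts, a mean of at least 10 CPM, DESeq2 1.42.0, limma-voom, glmTreat against a fold of 1.5, an estimated correlation, and leaving out each library in turn. Alternatives chosen after seeing the data were doxorubicin library 3 alone against stretch, voom with library quality weights, EIF4A2 and TAF1D left out, symbols in several rows left out, and a GC correction per library. Medians of a list under an alternative are over the members tested with all libraries, a choice made for the interferon list after its median over all members tested there had been seen. With doxorubicin library 3 alone, the lone doxorubicin library is assumed to vary like the stretch libraries.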

Results

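Gene expression was measured in A549 cells, an epithelial line derived from a human lung adenocarcinoma. The cells had been treated in either of 2 ways and then sorted for β-galactosidase, an enzyme whose staining is used as a marker of senescent cells. In 3 libraries the treatment was doxorubicin, a topoisomerase II poison that breaks DNA, at 100 nM for 24 h. In 4 libraries the cells had been stretched cyclically for 24 h, at 15% elongation and 15 cycles per min. Staining followed after 6 days, and RNA came from the positive cells of both groups. The comparison asks how stretched senescent cells differ from cells made senescent by a drug that damages DNA. No untreated cells were analysed here, so "higher in doxorubicin" and "lower in stretch" are the same statement. The labels do not say whether the replicates came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

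The deposited table held estimated counts for 14647 rows. Total counts were 3453357, 2611766 and 4644650 in doxorubicin libraries 1, 2 and 3, and 5636494, 7419798, 7407382 and 7243024 in stretch libraries 4, 5, 6 and 7. A single gene, EIF4A2, which codes a translation initiation factor and hosts small nucleolar RNAs in its introns, took 16.1%, 30.6% and 10.8% of the counts of doxorubicin libraries 1, 2 and 3. Its share was between 1.67% and 2.87% in the stretch libraries. Rows at a count of 0 made up 10.9%, 21.4% and 5.10% of the table in doxorubicin libraries 1, 2 and 3, and 4.17% to 4.88% in stretch. A level of 3 counts, taken as detection, corresponded to 2.59 CPM in doxorubicin library 2 and to between 0.321 and 0.401 CPM in the stretch libraries. Pearson correlations of log-CPM across genes were 0.939 to 0.978 between stretch libraries, 0.754 to 0.884 between doxorubicin libraries and 0.724 to 0.941 between the groups. Doxorubicin library 3 correlated with stretch library 4 at 0.941, more closely than with doxorubicin libraries 1 and 2, at 0.882 and 0.754. The first principal component took 69.1% of the variance and set doxorubicin library 2 and, less far, doxorubicin library 1 apart from the other 5 libraries.

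**Figure D1:**
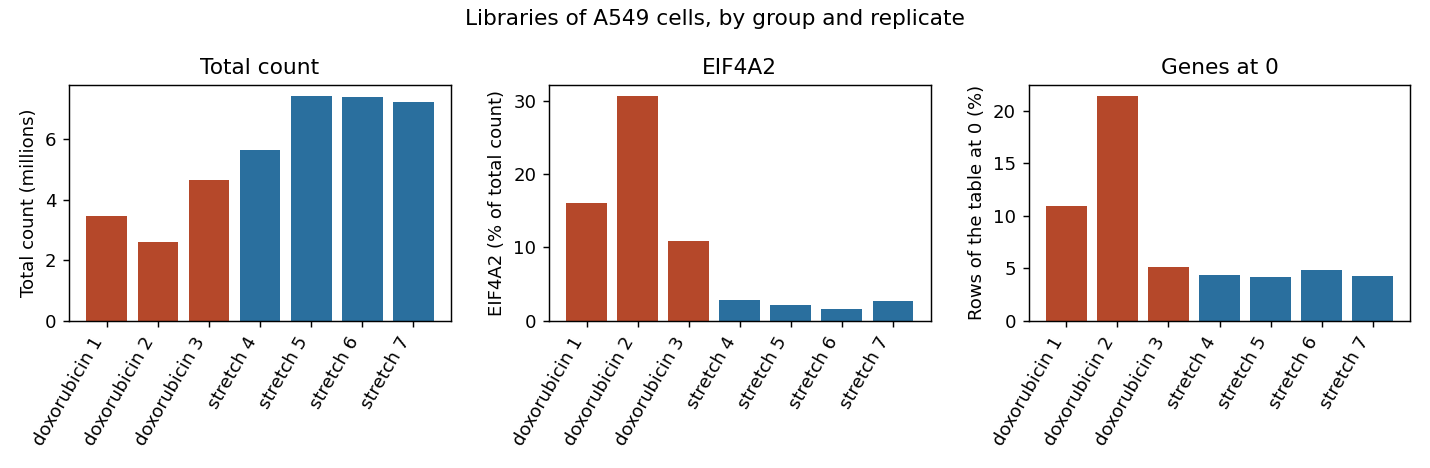
Bars give, for each of the 3 doxorubicin (red) and 4 stretch (blue) libraries, the total count, the share of that count taken by EIF4A2 in percent, and the share of table rows at 0 in percent. Doxorubicin library 2 has the lowest total, 2611766, the highest EIF4A2 share, 30.6%, and the most rows at 0, 21.4%.

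Interferon-stimulated genes, the antiviral programme that cells switch on downstream of interferon receptors, were the clearest difference and were higher after doxorubicin. All 27 tested members of the list lay on that side, 17 of them past the threshold, with a median log2 fold change (stretch minus doxorubicin) of -2.48. MX1, a GTPase that blocks viral replication (chromosome 21, 41420304 to 41459214), stood at 98.3 ± 55.9 CPM (SD, n = 3) after doxorubicin and 1.18 ± 0.46 CPM (n = 4) after stretch, an 82.3-fold difference. ISG15, a ubiquitin-like modifier (chromosome 1, 1001138 to 1014540), stood at 363 ± 192 against 6.20 ± 0.88 CPM, and IFI6 at 352 ± 239 against 11.6 ± 1.32 CPM. IRF7, the transcription factor that amplifies interferon production, was 41.0-fold and BST2, which tethers budding virions, 31.0-fold higher. ISG15 had the lowest adjusted p of the list, 0.000707 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (log2 fold change -5.87, SE 0.45). The log2 fold change of IFI6 was -4.92, and -4.20 without doxorubicin library 1. A total of 23 members passed when adjusted over the list alone. By camera the list had an adjusted p of 2.03e-23 against all other genes with a preset correlation, and adjusted p = 0.0911 with an estimated correlation. With doxorubicin library 3 as the only doxorubicin library, the median of the same 27 members was -1.99, all 27 on the doxorubicin side.

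Over the whole transcriptome, 261 of 11230 tested genes passed an adjusted p of 0.05 in edgeR's quasi-likelihood test, 221 higher in doxorubicin and 40 higher in stretch, and each differed more than 2-fold. Among the 182 of these with a mean of at least 10 CPM and no overlap between groups, the largest differences toward doxorubicin outside the interferon-stimulated genes were those of USP17L9P, NRSN1, FLNC, CACNG4 and RASGRP1, with log2 fold changes from -5.83 to -4.34. CACNG4, a calcium channel subunit, stood at 89.8 ± 98.6 CPM against 4.17 ± 0.56 CPM, and RASGRP1, an exchange factor for Ras, at 28.7 ± 32.7 against 1.30 ± 0.59 CPM. CACNG4, RASGRP1 and NRSN1 were highest in doxorubicin library 2, at 201, 65.7 and 57.9 CPM, and their log2 fold changes were -2.98, -2.86 and -2.94 without that library and -1.80, -1.57 and -1.94 with doxorubicin library 3 alone. The log2 fold change of USP17L9P was -4.32 without doxorubicin library 1 and that of FLNC -3.81 without doxorubicin library 2, and with doxorubicin library 3 alone they were -3.51 and -2.59. USP17L9P belongs to a multicopy family of near-identical genes, so its counts are uncertain. The group ranges of 2400 genes (21.4%) did not overlap, where chance gives 5.71%, and these included 259 of the 261. Without doxorubicin libraries 1 and 2, an analysis chosen after seeing the data, 99 genes passed, 89 higher in doxorubicin and 10 in stretch, and 63 of them were among the 261. The count moved with single libraries: it was 23, 289 and 3736 without doxorubicin libraries 1, 2 and 3, and 40, 16, 12 and 12 without stretch libraries 4, 5, 6 and 7. In every one of the 7 sets that leave out a library, 12 genes passed, 8 of them on the interferon list.

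Genes of the senescence-associated secretory phenotype, the mix of cytokines, proteases and growth factors that senescent cells release, were higher after doxorubicin where they passed the test. Of 14 tested cytokines and chemokines, 3 passed, all higher in doxorubicin, and the list's median was -0.95. CCL2, which attracts monocytes, stood at 262 ± 12.4 CPM after doxorubicin and 45.2 ± 7.89 CPM after stretch, and was past the threshold in each of the 7 sets that leave out a library. IL6 (chromosome 7, 22725884 to 22732002) stood at 11.1 ± 2.80 against 1.27 ± 0.73 CPM, and IL11 at 36.3 ± 24.1 against 4.38 ± 1.49 CPM. The log2 fold change of IL11 was -3.01, and -2.35 without doxorubicin library 2. CXCL8 did not pass, at 121 ± 78.8 against 55.1 ± 24.98 CPM. Of 24 tested proteases and growth factors, 3 passed: MMP2, MMP7 and SERPINE2, with log2 fold changes of -3.63, -1.63 and -2.49. MMP2 stood at 20.6, 98.6 and 8.32 CPM in doxorubicin libraries 1, 2 and 3, and its log2 fold change was -2.09 without library 2 and -1.32 with library 3 alone. SERPINE2 had -1.91 and -0.43 in the same settings, and in library 3 it stood at 65.03 CPM against 37.2 to 58.4 CPM in stretch. Adjusted over the list alone, 5 cytokines and 9 proteases and growth factors passed, all higher in doxorubicin. Camera's adjusted p was 0.00141 for the cytokines and 6.04e-05 for the proteases, and adjusted p = 0.113 with an estimated correlation for each. The medians were -0.95 and -0.89 with all libraries, and -0.67 and -0.44 with doxorubicin library 3 alone.

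Cytoskeletal, matrix and growth factor genes that are often studied as targets of mechanical force were mostly higher after doxorubicin where they passed, with FST the exception. In the list of actin cytoskeleton and SRF targets (SRF is the transcription factor that couples actin dynamics to transcription), FLNC, TAGLN and PDLIM7 passed among 18 tested members, with log2 fold changes of -4.58, -3.85 and -2.34, and 16 members lay on the doxorubicin side. TAGLN was weakly expressed, at 7.36 ± 1.89 against 0.48 ± 0.23 CPM. Among 23 tested YAP/TAZ targets, read-outs of the mechanosensitive Hippo pathway, TGFB2, FSTL1 and DLC1 passed on the doxorubicin side, with log2 fold changes of -2.27, -1.71 and -2.48. The classical targets CYR61 (CCN1) and CTGF (CCN2) did not pass, at log2 fold changes of -0.49 and -0.94. Of 24 matrix and basement membrane genes, SPARC, COL6A2 and COL5A1 passed, each between 4.64-fold and 4.91-fold higher in doxorubicin. In the TGF-beta and profibrotic list of 23 tested genes, TGFB2, LTBP3 and PDGFB were higher in doxorubicin, as was PDGFA (log2 fold change -1.34), named after its value was seen. The log2 fold change of LTBP3 was -2.52, and -1.76 without doxorubicin library 2. FST, the activin antagonist follistatin, was higher in stretch, at 23.0 ± 4.57 against 5.59 ± 1.44 CPM. Adjusted over the list alone, 11 actin, 9 YAP/TAZ, 9 matrix and 10 TGF-beta members were higher in doxorubicin, and 3 TGF-beta members in stretch. Camera's adjusted p was 4.52e-06 for actin, 0.000105 for YAP/TAZ, 0.000284 for matrix and 0.00851 for TGF-beta genes. In the same order, these became adjusted p = 0.166, 0.173, 0.0911 and 0.173 with an estimated correlation. The medians were -1.28, -0.89, -0.74 and -0.76 with all libraries, and -0.25, -0.32, -0.73 and -0.33 with doxorubicin library 3 alone.

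**Figure D2:**
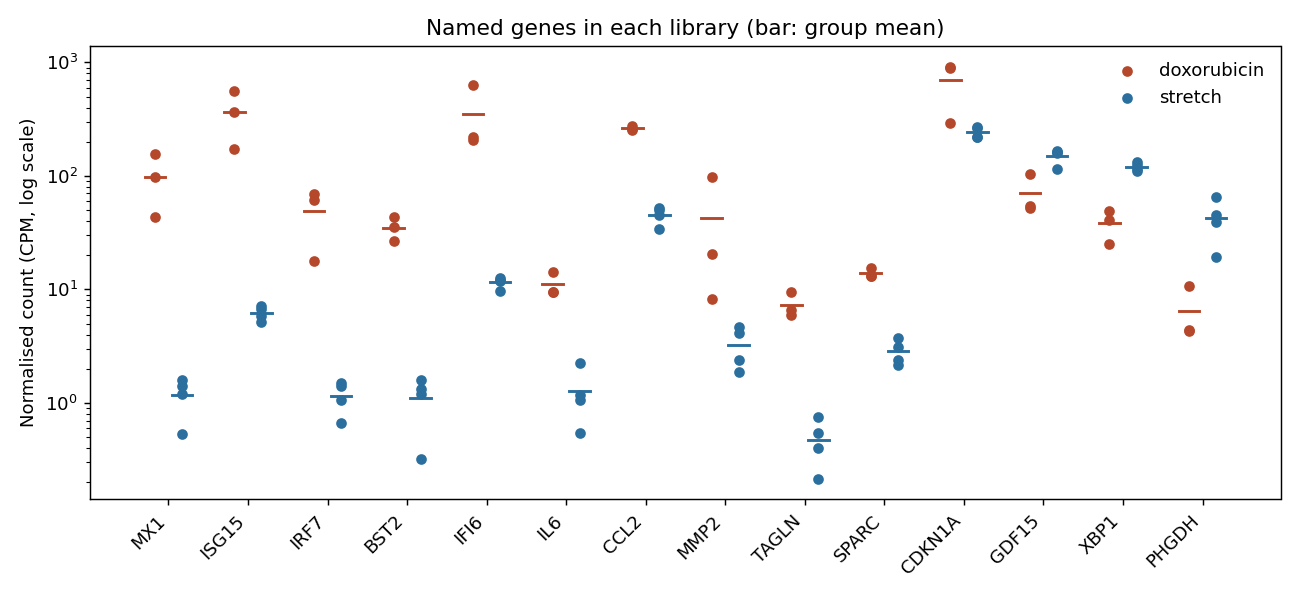
Points give the normalised count (CPM, log scale) of 14 named genes in each of 3 doxorubicin (red) and 4 stretch (blue) libraries, and bars the group means. The interferon-stimulated genes MX1, ISG15, IRF7, BST2 and IFI6 separate the groups in every library, while CDKN1A and GDF15, which did not pass the test, lie closer together.

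Genes higher in stretch were fewer when all libraries were used. With a mean of at least 10 CPM and no overlap between groups, the first 10 by size were PHGDH, PON2, ERP29, SEC11A, APOH, INSL4, SPDEF, FGL1, MRPS30 and FST, each at least 4.03-fold higher. None of them passed without doxorubicin library 1 or without stretch library 5, 6 or 7, where 0, 1, 0 and 0 genes were higher in stretch by edgeR (596 to 634 at an unadjusted p under 0.05 where the count was 0). Without stretch library 4 the count was 11. Without doxorubicin library 3, 1858 genes were higher in stretch and 1878 in doxorubicin (1791 and 1651 over 2-fold). PHGDH, the first enzyme of serine synthesis (chromosome 1, 119648411 to 119744226), stood at 42.3 ± 18.6 CPM after stretch and 6.49 ± 3.71 CPM after doxorubicin. PON2, a lactonase with antioxidant activity, stood at 183 ± 65.4 against 31.9 ± 12.8 CPM, and INSL4, a relaxin-family peptide, at 287 ± 60.9 against 61.6 ± 32.7 CPM. ERP29, a chaperone of the endoplasmic reticulum, and SEC11A, a subunit of the signal peptidase, were 5.44-fold and 4.90-fold higher. In doxorubicin library 2, PHGDH, ERP29, SEC11A, MRPS30 and FST had 5, 4, 4, 2 and 5 counts, around the detection level of 3. The rest of the first 10 had 14 to 28 counts there. In the list of the integrated stress response and unfolded protein response, 23 of 25 tested members lay on the stretch side and 2 passed, PHGDH and XBP1, the transcription factor that expands secretory capacity (log2 fold change 1.64). PDIA4 and PSAT1, which did not pass, had log2 fold changes of 2.10 and 2.14. Without doxorubicin library 3 the log2 fold changes of PHGDH, ERP29, SEC11A, PDIA4 and PSAT1 were 3.30, 3.15, 3.33, 2.72 and 2.96. Their lowest values over the alternatives were 1.99, 1.74, 1.44, 1.57 and 1.29. Among 21 genes of cholesterol synthesis, INSIG1, a sterol-regulated brake on the pathway, was 3.04-fold higher, and 18 lay on the stretch side. Adjusted over the list alone, 10 stress response genes and 2 cholesterol genes passed, all higher in stretch. Camera's adjusted p was 9.18e-05 for the stress response (median 0.87) and 0.000776 for cholesterol synthesis (median 0.80). These became adjusted p = 0.305 and 0.0911 with an estimated correlation. Against doxorubicin library 3 alone the medians were 0.97 and 0.53.

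CDKN1A and GDF15, genes much used as markers of senescence and stress, did not pass the test, although the group ranges of each did not overlap. CDKN1A, which codes the cell cycle inhibitor p21, stood at 703 ± 356 CPM after doxorubicin and 244 ± 28.2 CPM after stretch (log2 fold change -1.52, SE 0.39, adjusted p = 0.0651 by edgeR). GDF15, a stress-induced cytokine, stood at 70.3 ± 29.2 against 151 ± 24.2 CPM (log2 fold change 1.10, SE 0.34, adjusted p = 0.0985 by edgeR). Each passed in 3 of 19 alternatives, with adjusted p from 1.67e-06 to 0.670 for CDKN1A and from 0.0146 to 0.254 for GDF15, and the log2 fold change of CDKN1A was -0.24 with doxorubicin library 3 alone. LMNB1, MKI67 and GLB1, which codes the lysosomal β-galactosidase, had log2 fold changes of 0.89, -0.31 and -0.15. LMNB1, whose loss is used as a sign of senescence, had 1, 0 and 53 counts in doxorubicin libraries 1, 2 and 3, and its level in library 3, 10.02 CPM, lay within the stretch range of 5.99 to 11.9 CPM (log2 fold change 4.86 without that library). CDKN2A was not analysed here. The list of senescence-arrest markers and that of mitosis, with 14 and 30 tested members, had no member past the threshold, although camera placed both toward stretch, each with an adjusted p of 0.0337. These became adjusted p = 0.305 and 0.725 with an estimated correlation. Their medians were 0.62 and 0.24 with all libraries, and 0.22 and -0.30 with doxorubicin library 3 alone. The senescence-arrest list holds markers that are lost in senescence, such as LMNB1, beside others that are not, such as GLB1. Its direction therefore does not tell which group was more arrested. In edgeR's quasi-likelihood test the count of called members was also 0 for DNA replication, homologous recombination and Fanconi repair, replication-dependent histones, immediate early genes, NRF2 targets, hypoxia and glycolysis, and nuclear-encoded oxidative phosphorylation. In that order, their medians were -0.29, 0.12, 0.31, 0.16, 0.36, -0.08 and 0.38, and with doxorubicin library 3 alone -0.51, -0.57, -0.06, 0.46, 0.51, 0.05 and 0.23. In that setting 27 of 29 replication genes and 19 of 21 recombination and Fanconi genes lay on the doxorubicin side, and 1 of the latter passed. The zeros moved: without doxorubicin library 3, edgeR called 9, 5, 7, 9, 13, 3 and 6 members in the same order, and voom with library quality weights 9, 6, 9, 12, 20, 9 and 13. Of all tested genes, 3736 of 11618 passed in the former setting and 5303 of 11230 in the latter. Across the 14 lists with a count of 0, which hold 257 genes, 51 genes had an unadjusted p under 0.05, DESeq2 called 22 and limma-voom 0. Among all 11230 genes tested by edgeR, 2604 had an unadjusted p under 0.05. DESeq2 called 1315 of 13112 genes and limma-voom 186 of 11230.

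Other groups differed by single genes. Among antigen presentation genes HLA-B, at 7.81 ± 3.83 against 0.93 ± 1.09 CPM, did not pass (log2 fold change -3.15, and -4.28 without stretch library 4). It is polymorphic, so its counts are uncertain. Camera's adjusted p for the 14 antigen presentation genes (median -0.66, and -0.58 with doxorubicin library 3 alone) was 0.0251, and adjusted p = 0.166 with an estimated correlation. Of these, 5 passed, all higher in doxorubicin, when adjusted over the list alone. The keratins KRT80 and KRT18, the small heat shock protein CRYAB, the lysosomal saposin precursor PSAP and the integrin subunit ITGA3 were higher in doxorubicin, each in a list that did not pass camera. These were epithelial junctions and keratins (19 tested), the heat shock response (17), the lysosome (31), and ion channels and mechanosensors (26), with medians of -0.42, 0.02, -0.17 and -0.27, and of 0.19, -0.20, 0.47 and 0.07 with doxorubicin library 3 alone. PIEZO2, a stretch-activated channel, did not pass, at 61.1 ± 50.1 against 13.9 ± 2.95 CPM (log2 fold change -2.10, and -1.20 without doxorubicin library 2). Of 14 mesenchymal markers (median -0.66, and -0.04 with doxorubicin library 3 alone) MMP2 alone passed. Of 12 alveolar type I and transitional markers (median -0.26, and -0.18 with doxorubicin library 3 alone) GPRC5A alone passed, higher in stretch at 51.5 ± 6.61 against 16.8 ± 6.34 CPM. Adjusted over the list alone, the epithelial list had 2 members higher in doxorubicin and 1 in stretch, the mesenchymal list 6 and 1, and the mechanosensor list 5 and 2. Camera's adjusted p for the 16 lists that did not pass lay between 0.0887 and 0.891. The median, the mean and camera differed in sign for immediate early genes (median 0.16, mean -0.03, camera toward doxorubicin), for hypoxia and glycolysis (median -0.08, mean 0.02, camera toward doxorubicin) and for dead or stressed cell transcripts (median 0.05, mean 0.13, camera toward doxorubicin).

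**Figure D3:**
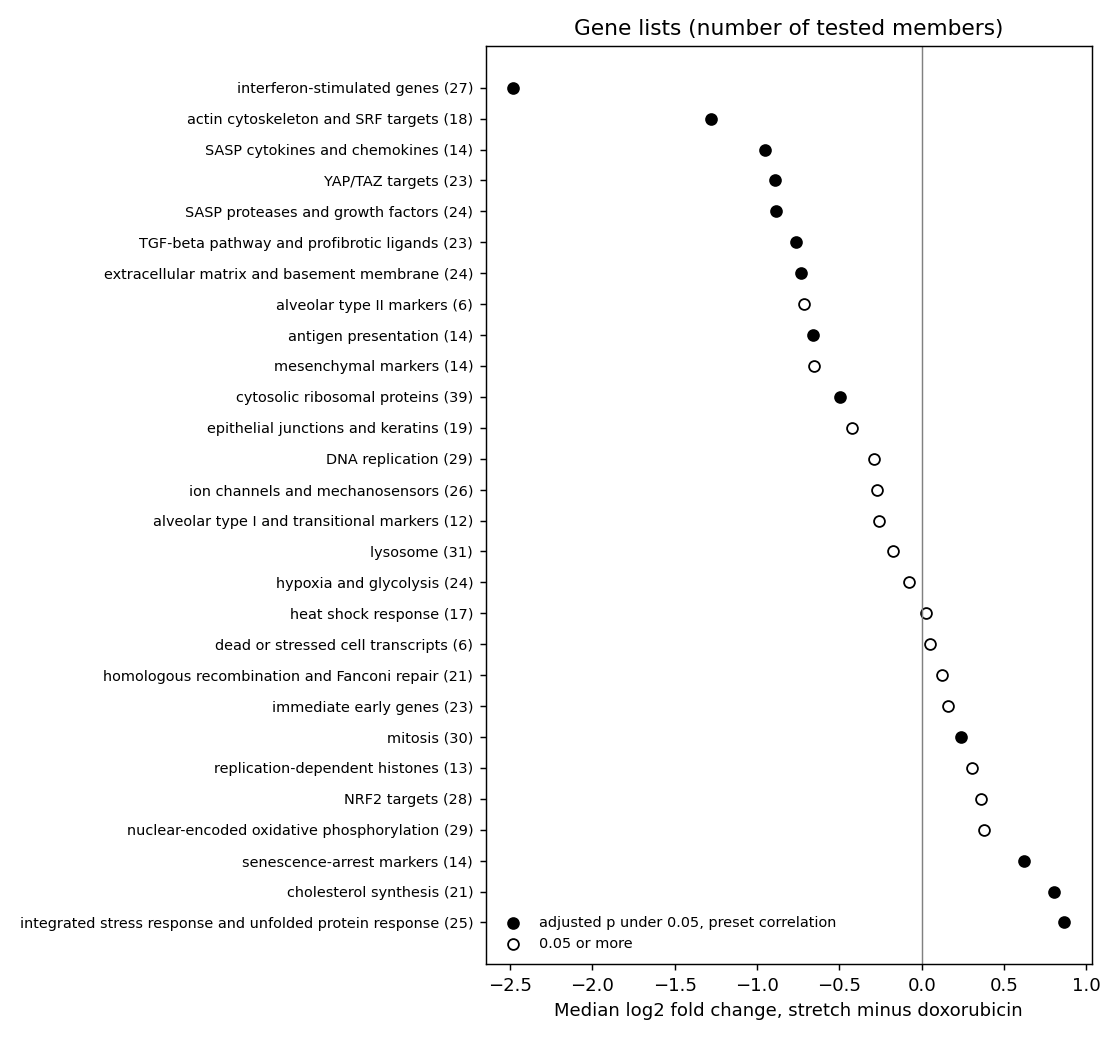
Each point is the median log2 fold change, stretch minus doxorubicin, of the tested members of a gene list, with their number in parentheses, for 28 of the 29 lists with at least 5 tested members. Filled points passed camera with the preset correlation (0 of 29 with an estimated correlation), and the interferon-stimulated genes lie farthest from 0, at -2.48.

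Markers of other cell types and genes that track library composition were as follows. Of the 4 tested leukocyte markers CD68, a lysosomal protein that epithelial lines also express, was higher in doxorubicin, at 75.6 ± 28.7 against 18.6 ± 1.44 CPM. None of 4 fibroblast, 2 endothelial and 6 alveolar type II markers passed edgeR's test, and their medians were -0.91, 0.37 and -0.72, and -0.05, 0.12 and 0.07 with doxorubicin library 3 alone. Among them, THY1 stood at 16.7 ± 8.34 against 5.92 ± 1.51 CPM and LPCAT1, of alveolar type II cells, at 148 ± 27.1 against 73.6 ± 23.2 CPM. Of 6 transcripts of dead or stressed cells, all mitochondrial, none passed (median 0.05, and 0.51 with doxorubicin library 3 alone). Mitochondrial transcripts took at most 0.0110% of the counts of any library. At such low counts the list could not tell whether the groups differed in dead or stressed cells. EIF4A2 and TAF1D, both hosts of small nucleolar RNAs and named after their values were seen, were higher in doxorubicin, with log2 fold changes of -4.21 and -2.43, which were -3.11 and -1.78 without doxorubicin library 2 and -2.37 and -1.68 with doxorubicin library 3 alone. Among 39 cytosolic ribosomal protein genes, RPS2, RPL10 and RPL23 were higher in doxorubicin, with log2 fold changes of -3.20, -2.28 and -1.70, and RPL8 was higher in stretch, at 1.78. Without doxorubicin library 2, RPS2 had -2.54. Ribosomal protein genes have many processed pseudogenes, so their counts are uncertain. When adjusted over the list alone, 5 were higher in doxorubicin and 1 in stretch. Camera's adjusted p for this list was 0.0132, and adjusted p = 0.490 with an estimated correlation. Its median was -0.50 with all libraries and 0.37 with doxorubicin library 3 alone. Of the 29 lists tested, 13 passed camera with the preset correlation, 0 with an estimated correlation (8 at an unadjusted p under 0.05) and 11 by fry, which asks whether a list's genes move on balance in a single direction.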

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

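Within the 4 stretch libraries, 96 quantities were tested for a library far from the other 3, relative to the range of the group, and 7 were found, where chance alone gives about 1 in 20. Doxorubicin, with 3 libraries, was not tested. Stretch library 4 gave 5 of the 7. Its total count, 5636494, lay below the others, with a gap of 0.901 of the range. Its share of counts in ribosomal protein genes, 19.3%, was the lowest (gap 0.855), and its share in mitochondrial transcripts, 0.0110%, the highest (gap 0.936). TRIB3 and SLC3A2, named after their values were seen, were lowest in the same library, with gaps of 0.890 and 0.913. GDF15 was lowest in stretch library 6, at 115 CPM against 160 to 167 CPM (gap 0.873). PDGFB was lowest in stretch library 7, at 0.430 CPM, or 4 counts, against 1.34 to 1.51 CPM (gap 0.886).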

How the results depend on the processing

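The runs with doxorubicin library 3 alone, library quality weights, a GC correction, and with EIF4A2 and TAF1D or repeated symbols left out were chosen after seeing the data. All 261 calls kept their sign in every setting that tested them. The interferon list passed camera in all settings run except with an estimated correlation. What makes the counts move was not tested. Genes higher in doxorubicin and in stretch numbered 910 and 405 with DESeq2 (865 and 361 over 2-fold, 1315 in all, including the 261), 11 and 2 with library totals alone, which move the median of all genes by 0.71, 127 and 20 with a mean of at least 10 CPM, where 77 calls were not tested, 74 and 1 with glmTreat, 89 and 10 with doxorubicin library 3 alone, and 2677 and 2626 with quality weights (1452 and 1697 over 2-fold). With the GC correction, 78 genes were higher in stretch. Leaving out each library gave 12 to 1878 genes higher in doxorubicin (12 to 1651 over 2-fold) and 0 to 1858 higher in stretch (0 to 1791 over 2-fold). The 3 edgeR runs with 0 had 596 to 634 genes on that side at an unadjusted p under 0.05. Of the followed genes, 62 passed the threshold, and 8 of them did so in all 7 runs that leave out a library. Leaving out a library moved 30 of the 90 followed genes by more than 1.5-fold. Interferon-stimulated genes called were 28 of the 33 members that DESeq2 tested, 7 with library totals alone, and 8 to 23 without a library.

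With an estimated correlation camera's adjusted p was 0.0911 for the interferon, matrix and cholesterol lists, 0.113 for both secretory lists, 0.166 for actin and antigen presentation, 0.173 for YAP/TAZ and TGF-beta, 0.305 for the stress response and senescence-arrest, 0.490 for ribosomal proteins and 0.725 for mitosis. With a mean of at least 10 CPM it was 0.0694 for mitosis, 0.0643 for secretory cytokines, 0.114 for senescence-arrest and 0.0716 for TGF-beta. It was 0.167 for mitosis with library totals alone, 0.253 for antigen presentation without repeated symbols, and 0.142 for mitosis and 0.0575 for antigen presentation with the GC correction. With doxorubicin library 3 alone, mitosis (0.0553) and ribosomal proteins (0.432) changed direction, and senescence-arrest (0.156) and TGF-beta (0.0843) did not pass. Leaving out each library gave 0.000598 to 0.491 for mitosis, 0.0176 to 0.0802 for senescence-arrest, 0.00977 to 0.0969 for antigen presentation and 0.00105 to 0.0971 for ribosomal proteins. Among named genes not past the threshold, the log2 fold change changed sign for LMNB1 (-0.28) and IFNE (-0.67) with doxorubicin library 3 alone, for GLB1 there (0.68) and with library totals alone (0.72), for MKI67 with library totals alone (0.41) for CYR61 with quality weights (0.017), for TRIB3 with library totals alone (0.84), limma-voom (0.038), doxorubicin library 3 alone (1.31), quality weights (0.33) and the GC correction (0.078), and for SLC7A11 with library totals alone (0.64) and no filter on low counts (0.024). Leaving out each library gave -0.42 to 0.064 for GLB1, -0.86 to 0.47 for CYR61, -0.038 to 1.62 for IFNE, -0.66 to 0.69 for TRIB3 and -0.22 to 0.12 for SLC7A11.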

Other observations

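Tests chosen only after the result was seen are those of the interferon list in doxorubicin library 3 alone and under a GC correction, of host genes in library 3 alone and by their calls and shares, of the depth of library 1 at either depth, and of the tRNA synthetases. Most tested genes of a further list, inducible by interferon but outside the fixed list, also lay on the doxorubicin side. Of 29 tested genes of this list, written after the calls were seen and so not independent evidence, 15 passed edgeR's test and 27 lay on the doxorubicin side. Their median was -1.63, and -0.94 with doxorubicin library 3 alone. TRIM22, an antiviral ubiquitin ligase, stood at 79.3 ± 22.1 CPM (n = 3) against 9.26 ± 2.87 CPM (n = 4). Of the complement genes, CFB stood at 90.0 ± 43.6 against 8.12 ± 2.44 CPM and C1S was 3.73-fold higher, and IFITM3, UBA7, IFI16 and PARP12 passed as well (IFITM3 at -3.00 and IFI16 at -2.38, and -2.36 and -1.74 without doxorubicin library 1). Of 12 tested ligands, receptors and sensors of the pathway, edgeR called 0 (3 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom), with a median of 0.027. Only IFNA1 and IFNE among them code interferons, so these values do not tell whether interferon production differed. IFNE, an epithelial interferon, stood at 40.1 ± 40.2 against 53.6 ± 15.7 CPM, and MB21D1, which codes the DNA sensor cGAS, at 5.76 ± 4.603 against 16.4 ± 1.49 CPM (log2 fold change 1.34, and 2.20 without doxorubicin library 3). ABCB1, an exporter that can pump doxorubicin out of cells, was 5.88-fold higher in doxorubicin, at 6.34 ± 1.25 against 1.02 ± 0.70 CPM. Its log2 fold change was -2.56, and ran from -3.14 (without stretch library 6) to -1.83 over 18 alternatives. It passed in 10 of these.

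The pattern that the interferon-stimulated genes were higher after doxorubicin was weighed against poor libraries and GC bias. With doxorubicin library 3 alone the list's median was -1.99 and its camera adjusted p 1.03e-27 (3.06e-38 to 0.0911 over the alternatives), which argues against libraries 1 and 2 as its whole source. After a correction for whole-transcript GC the median was -2.66, which argues against a bias that follows it. A bias from the GC content of the short amplified stretches, which was not measured, stays open. Chance alone is an unlikely source: of the 35 splits of the 7 libraries into 3 and 4, only 1, the real split, called as many members in a single direction (17, highest other 0), and only 1 called as many genes (261, highest other 1). Doxorubicin itself, stretch itself and any batch that separates the 2 groups stay open, since all of these follow the groups. Without untreated cells, a rise after doxorubicin cannot be told from a fall after stretch. Library 3 also had an EIF4A2 share of 10.8%, so it does not exclude a batch of the doxorubicin libraries.

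EIF4A2, TAF1D, RPS2, RPL10 and RPL23 host small nucleolar RNAs, which raised the hypothesis that host genes as a class were higher in the doxorubicin libraries. Leaving out EIF4A2 and TAF1D, the median of 195 hosts was -0.095, above -0.21, the 2.5th percentile of 10000 random sets matched on expression, which argues against a shift of the whole class. On the doxorubicin side 11 of 197 hosts passed against 210 of 11033 other genes (two-sided Fisher's exact p = 0.00178, chosen after seeing the calls), or 9 of 195 without EIF4A2 and TAF1D (p = 0.0142) and 6 of 192 without all 5 genes that raised the hypothesis (p = 0.189), and the hosts' share of counts was 14.4% to 15.7% in doxorubicin against 10.7% to 11.2% in stretch without those 2, and 9.06% to 10.1% against 9.10% to 9.70% without all 5. Whether ribosomal protein genes rather than hosting carry it stays open: the 168 hosts that code no ribosomal protein had a median of -0.0023, but the 27 that do had -0.52, also within the random range, which ends at -0.64. Against doxorubicin library 3 alone the median of hosts was 0.044, which decides nothing where the class had no shift to lose, and no biological explanation was tested.

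Doxorubicin libraries 1 and 2 stood apart from the other 5. Thinned to the effective depth of library 2, the stretch libraries still correlated with each other at 0.920 or more. This exceeded the highest correlation of library 2 with them by 0.134, which argues against read depth alone for library 2. For library 1, thinned in the same way, the excess was 0.042, and it was 0.048 at its own depth, both under the bound of 0.05 set for library 2, so depth stays open there. Whole-transcript GC content took 8.59% of the variance of the deviation of library 2 and 3.45% of that of library 1. These low shares argue against whole-transcript GC as the source. The GC content of the short amplified stretches was not measured, so a bias arising there stays open. The quality of the RNA was not tested, nor was the number of starting molecules, which thinning reads does not mimic. No biological explanation was tested.

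EPRS and SARS, which charge tRNAs with amino acids, were higher in stretch, with log2 fold changes of 1.78 and 1.81. Such enzymes are targets of ATF4, the transcription factor of the amino acid response, so the other 10 synthetases named as its targets were tested. Their median was 1.01, above 0.40, the level that 2.5% of 10000 random sets matched on expression exceed (0.61 against 0.48 with doxorubicin library 3 alone), and AARS and YARS, which did not pass alone, had 1.27 and 1.43 (YARS 2.09 without doxorubicin library 3). The 7 tested synthetases outside that group had a median of 0.46, within the random range, which ends at 0.62, and the difference between the 2 groups was not tested. The random sets hold unrelated genes and make no allowance for synthetases that vary together, so their ranges may be too narrow. ATF4 itself and its targets TRIB3, SLC7A11 and SLC3A2 did not pass, at 0.24, -0.27, -0.07 and 0.26. In the wider stress response list, 23 of 25 tested members lay on the stretch side and 2 passed. Camera's adjusted p for that list was 0.305 with an estimated correlation. A stronger amino acid response in the stretched cells stays a hypothesis, found and tested on the same data. ATF4 protein in both groups would have to be measured to decide it.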
